A study of Mus musculus with 2 samples.

How the data were processed

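Per the labels' protocols, total RNA was extracted with a silica column kit and made into libraries with standard Illumina protocols. The 2 libraries came from mouse embryonic stem cells (mESCs) of mixed 129SV/C57BL/6 strain, 1 wild type and 1 lacking Setd2, at passages 10 to 12. Per the labels' protocols, the cells grew on feeder cells. They were plated on gelatin for 0.5 h to let feeder cells attach, passaged once more on gelatin and collected 2 days later. Each library was taken to its group by its genotype label, and each column of the table by its name.

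Per the submitters' processing notes, CASAVA 1.6.0, TopHat 1.0.13 and the mm9 build were used, with no role or order stated. How reads with several alignments were counted, and whether strand was used, was not given in the sources used here. The deposited table has 17827 rows with a gene symbol, a gene number and a position, and 69 of them are unnamed loci numbered NEWGENE. Per the file headers the values are RPKM, but the values themselves did not have that scale. They were read as log2(x + 1), where x is the number of sequenced bases over the gene in units of 76 bases, called read equivalents here, with no scaling by depth or gene length. Among values of x above 0 and under 200, 85.9% in the wild-type library and 85.7% in the knockout library were whole multiples of 1 base out of 76, within 0.05 of a base. The step by which the authors made the deposited log2 values is not given in the sources used here. No other column of per-sample values was present.

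The log2 values were turned back into read equivalents and divided by the library total over all gene rows and scaled to a total of 1000000 (CPM). A symbol on several rows took the row with the highest mean, which left 17817 genes. The fold was log2((knockout + 0.5)/(wild type + 0.5)) on CPM, so folds of low genes are understated. Genes with a mean of at least 1 CPM over both libraries were compared, and counts of genes used a 2-fold threshold. With 1 library per group there was no replicate of either genotype. No p-value, standard error or count of significant genes was therefore computed, and every difference describes these 2 libraries only. Beside named genes stands the ratio of the CPM levels without a pseudocount, with an exact conditional binomial 95% interval on rounded read equivalents. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Genes at exactly 0 are given as listed at 0, with no fold.

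Gene lists were fixed before the data were examined. For each list with at least 5 members over the floor, the median fold was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level. The percentile is a description of these libraries. Genes were named by a rule fixed at the same time. It took Setd2, the 12 highest and the 12 lowest folds among genes with a mean of at least 5 CPM, up to 4 members of each list with the largest absolute fold, and 13 list-defining genes. Predicted genes, clone names, small RNAs and pseudogenes were only counted. Genes named outside that rule are marked as chosen after their values were seen.

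The positions were compared with the GENCODE annotation of the NCBIM37 assembly, the same assembly as mm9. Of the 17827 rows, 94.6% overlapped a gene model of the same symbol, 87.9% of these started within 1000 bases of it, and 0 rows ended beyond their chromosome. To find reads that could belong to several places, 20 windows of 76 bases from the exons of each gene were aligned to the genome with minimap2 2.31. A window counted as shared if it had another place with at most 2 mismatches or could not be placed at its own. Rows without a matching gene model used the whole span in the table, a choice made after the data were seen.

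The procedure was tested on simulated libraries with the depths and levels of the real pair, over 13505 genes. Of 100 genes set 3-fold apart, 98% passed the 2-fold threshold in the right direction, and of 100 genes set 1.5-fold apart, 0% did. None of the 13307 unchanged genes passed, a count of 0, and the interval held a ratio of 1 for 93.5% of them. The simulation holds counting noise only and no variation between cultures or lines, so these figures do not say how many of the genes apart in the real pair would differ again. All 20 simulated lists of 25 genes shifted by 0.5 lay above the 97.5th percentile, and 1 of 20 unshifted lists lay outside the central 95%.

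The alternatives were pseudocounts of 0.1 and 1, a floor of 5 CPM or none, thresholds of 1.5-fold and 3-fold, and summing the rows of a symbol. The knockout library was also rescaled to a median log2 ratio of 0, by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end) and to the same upper quartile. Leaving out chromosomes 8 and Y, and leaving out genes with shared windows, were added after the data were seen. The design had foreseen values on the header's scale or counts, and its rule for counts, scaled to CPM, was used. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.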

Results

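The transcriptomes of 1 wild-type and 1 Setd2 knockout line of mouse embryonic stem cells were sequenced, to ask which genes differ in level when Setd2 is missing. Setd2 encodes the enzyme that trimethylates histone H3 at lysine 36 over transcribed genes. The wild-type library held 56129838 read equivalents over genes and the knockout library 52041677. The 10 most abundant genes took 3.89% and 4.16% of them. At these depths 1 CPM stood for 56.1 read equivalents in the wild-type library and 52.0 in the knockout library. Neither genotype had a replicate.

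Setd2 itself (gene number 235626, chromosome 9, 110451132 to 110521137, mm9) was at 452 CPM in the wild-type library and 174 CPM in the knockout library, 38.5% of the wild-type level (95% counting interval 37.6 to 39.4%). The value is a total over the gene, and how the gene was disrupted is not given in the sources used here.

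Most genes stood close together in the 2 libraries. The 32 genes at least 8-fold apart outside chromosome Y, among those with a mean of at least 5 CPM, were mostly predicted genes or unnamed loci (18 of 32), with single genes such as Arhgap19, Meg3, Fosb and Cubn among the rest. Of 13523 genes with a mean of at least 1 CPM, 238 were at least 2-fold higher in the knockout library and 285 at least 2-fold lower, and 96.1% lay within 2-fold. The median log2 fold was 0.05. Chromosome 8 held 40 of the 285 lower genes and 2 of the 238 higher ones, against 5.32% of all genes compared. With a floor of 5 CPM the number of higher genes was 108, against 194 lower ones.

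**Figure D1:**
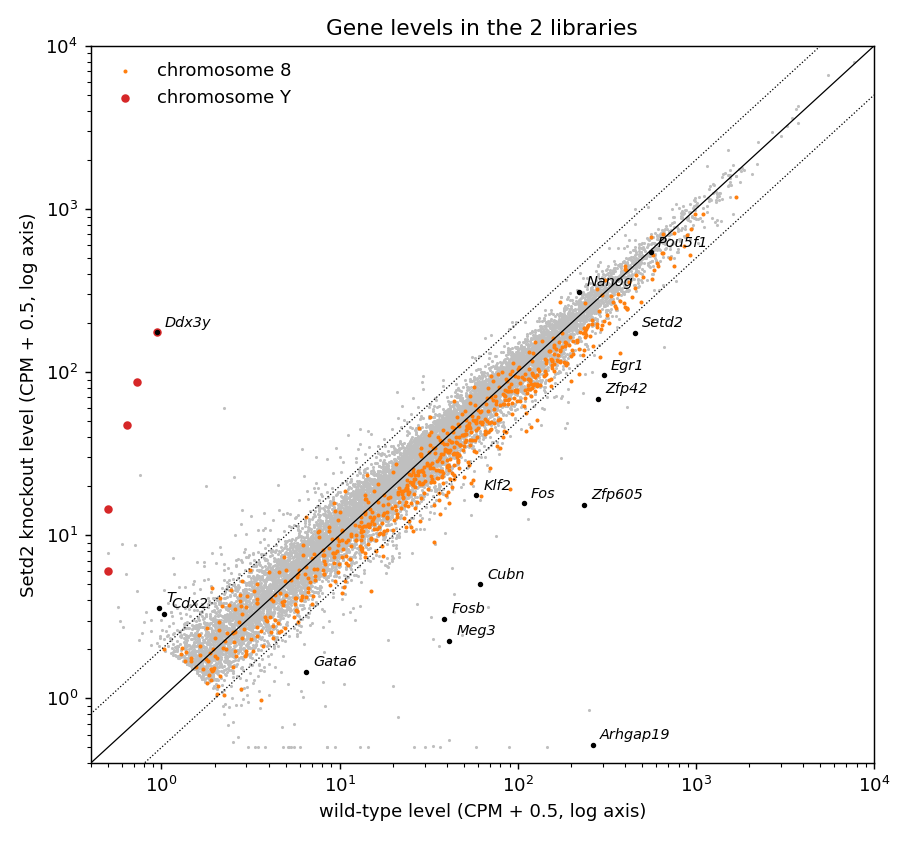
Level of each gene with a mean of at least 1 CPM in the wild-type library (horizontal) and the Setd2 knockout library (vertical), as CPM + 0.5 on log axes, with 1 point per gene. The solid line marks equal levels and the dotted lines 2-fold; chromosome 8 genes (orange) lie mostly below the solid line, with a median log2 fold of -0.35, and the 5 Y-linked genes (red) lie at the left edge.

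The 3 highest folds belonged to the Y-linked genes Ddx3y, Eif2s3y and Uty. Ddx3y, an RNA helicase gene, was at 0.445 CPM in the wild-type library and 176 CPM in the knockout library, 394-fold apart (interval 267 to 610). Eif2s3y, a translation initiation factor gene, was at 0.229 and 86.2 CPM, and Uty at 0.142 and 46.7 CPM. Ube1y1 and Zfy1 were listed at 0 in the wild-type library and were at 14.0 and 5.53 CPM in the knockout library. All windows of Ube1y1 and 65% of those of Zfy1 were shared with other places in the genome. Off the Y chromosome, Mthfd2l, a mitochondrial folate enzyme gene, was 5.88-fold higher in the knockout library (interval 4.88 to 7.15). The neurofilament gene Nefm was 4.83-fold higher, the lysosomal channel gene Mcoln3 4.66-fold, the ribosomal protein paralog Rpl39l 4.57-fold and Ahcy, which hydrolyses S-adenosylhomocysteine, 4.31-fold. For Mthfd2l 55% of windows and for Ahcy 70% were shared with other places, so their levels are uncertain. The unnamed loci NEWGENE10 (chromosome 12, 28104752 to 28105719), NEWGENE63 (chromosome 2, 108897694 to 108899154) and NEWGENE49 (chromosome 5, 74337577 to 74340134) overlapped no annotated gene. They were at 22.8, 22.4 and 19.7 CPM in the knockout library against 0.253, 2.06 and 4.03 CPM in the wild-type library, and 90% of the windows of NEWGENE10 and 65% of those of NEWGENE63 were shared.

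Among the lowest folds were genes with next to no reads in the knockout library. Arhgap19 (chromosome 19, 41844075 to 41876524) was at 264 CPM in the wild-type library and had 1 read equivalent in the knockout library, 0.00728% of the wild-type level (interval 0.000184 to 0.0406%). Tceal8 had 3 read equivalents in the knockout library and 40.8 CPM in the wild-type library, a ratio of 0.141% (interval 0.0291 to 0.414%). Trmt2a, a tRNA methyltransferase gene, the vomeronasal receptor gene Vmn2r53 and D16Ertd727e were listed at 0 in the knockout library, and had 2021, 3243 and 1438 read equivalents in the wild-type library. For Vmn2r53 40% and for D16Ertd727e 30% of windows were shared. Gene totals do not tell a missing transcript from one that was not counted. The zinc finger gene Zfp605 was at 236 and 14.9 CPM, 6.31% of the wild-type level (interval 5.86 to 6.78%). Ccnb1ip1, a meiotic crossover gene, was at 4.44%, the phospholipid transporter gene Abcb4 at 5.52% and the peptidyl-prolyl isomerase gene Ppia at 6.64%. Ppia, usually an abundant transcript, stood at only 43.4 CPM in the wild-type library too. In all, 21 genes were listed at 0 in the knockout library with at least 2 CPM in the wild-type library, and 3 the other way.

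Primitive endoderm genes were lower in the knockout library. Of 22 measured members, 9 were at least 2-fold lower and 1 at least 2-fold higher, with a median log2 fold of -0.63 at percentile 0.00. The endocytic receptor gene Cubn was at 7.38% of the wild-type level (interval 6.44 to 8.43%), the endoderm transcription factor gene Gata6 at 15.9% (11.6 to 21.6%), Pdgfra at 33.5% and the thrombomodulin gene Thbd at 36.1%. Gata4 was at 81.9% (71.4 to 93.8%). Sox17 and Foxa2 were below 1 CPM in both libraries. Chromosome 8 carried 3 of the measured members, and without chromosome 8 the median was -0.43. The mesendoderm list had a median of -0.18 over 9 members, at percentile 8.09, with Trh lower (-1.56). The primitive streak gene T was higher, 6.59-fold (interval 4.39 to 10.5), from 0.470 to 3.10 CPM. T passed the floor of 1 CPM only through the knockout library.

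Genes induced by ERK signalling were lower as a list, though not all feedback genes were, while genes of the pathway itself were not lower as a list. Of 27 target and feedback genes, 10 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.57 at percentile 0.00. Chromosome 8 carried 3 of the 10, Ier2, Junb and Dusp4, named after their values were seen, and without that chromosome the median was -0.53. The fibroblast list, standing for feeder cells, was lower as well (median -0.32). The immediate early transcription factor genes made up the low end, with Fosb at 6.76% of the wild-type level (interval 5.65 to 8.07%), Fos at 14.2% (13.1 to 15.3%), Egr2 at 7.62 CPM in the wild-type and 1.43 CPM in the knockout library and Egr1 at 31.3%. Feedback genes were mixed. The feedback phosphatase gene Dusp6 was 1.29-fold higher (1.26 to 1.32), with Spry1 at 0.55, Spry2 at -0.01 and Spry4 at -0.53. These Spry genes were named after their values were seen. Over the list, 23 members were below 0 and 4 above 0. Ligands, receptors and the RAS-ERK core had a median of 0.01 over 30 members, at percentile 31.8. Of these, 2 receptor genes were at least 2-fold lower, Fgfr3 at 39.8% (33.7 to 46.8%) and Fgfr4 at 45.1%, and the ligand gene Fgf4 had a log2 fold of -0.08.

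Pluripotency genes were slightly lower as a list, with 2 of 32 members at least 2-fold lower, 0 higher and a median of -0.19 at percentile 0.02. Both lower genes, Zfp42 at 24.1% of the wild-type level and Klf2 at 29.5%, lie on chromosome 8, and 60% of the windows of Zfp42 were shared with other places. Without chromosome 8 the median was -0.17. Utf1 and Mycn each had a log2 fold of -0.77. The core factor genes Pou5f1 and Sox2 were at 97.6% and 91.0%, and Nanog was 1.40-fold higher, with 55% of its windows shared. The rescalings moved the folds of all genes by under 0.1, and Nanog stayed above 0 and Sox2 below 0 in each.

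Apart from the Y-linked and Xist list, the 2-cell-like list stood highest, with 6 of 7 measured members at least 2-fold higher and a median of 1.79 at percentile 100. These 6 are the Zscan4 genes, expressed in a rare state of stem cell cultures, and 80 to 100% of their windows were shared with other places. As near-identical paralogs they do not count as 6 independent measurements. Zscan4f was at 0.662 and 6.73 CPM and Zscan4c at 1.03 and 4.77 CPM. All of these Zscan4 genes except Zscan4c were below 1 CPM in the wild-type library and passed the floor only through the knockout library. Of 18 list members with values, 7 passed the floor, so the count and the median rest partly on that high knockout level. With every gene above 0 included the median of the 2-cell-like list was 0.64. With a floor of 5 CPM the median was 0.63, from the single member left. Trophectoderm and placenta genes had a median of 0.36 over 12 members at percentile 99.1, with Cdx2 5.20-fold higher (3.52 to 8.06), from 0.539 to 2.80 CPM, and Igf2 2.10-fold. With every gene above 0 included that median was 0.043. Of 32 Hox genes listed, 5 passed the floor of 1 CPM, with a median of 0.61 at percentile 97.5, led by Hoxc13 at 1.24. Hoxd13, at 0.687 and 1.35 CPM, and Hoxb13, at 0.759 and 1.27 CPM, passed it only through the knockout library. Hoxb13 was named after its values were seen. Without Hoxd13 and Hoxb13 the list would hold fewer than the 5 members needed for a percentile. Cdx2, below 1 CPM in the wild-type library, passed the floor in the same way.

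**Figure D2:**
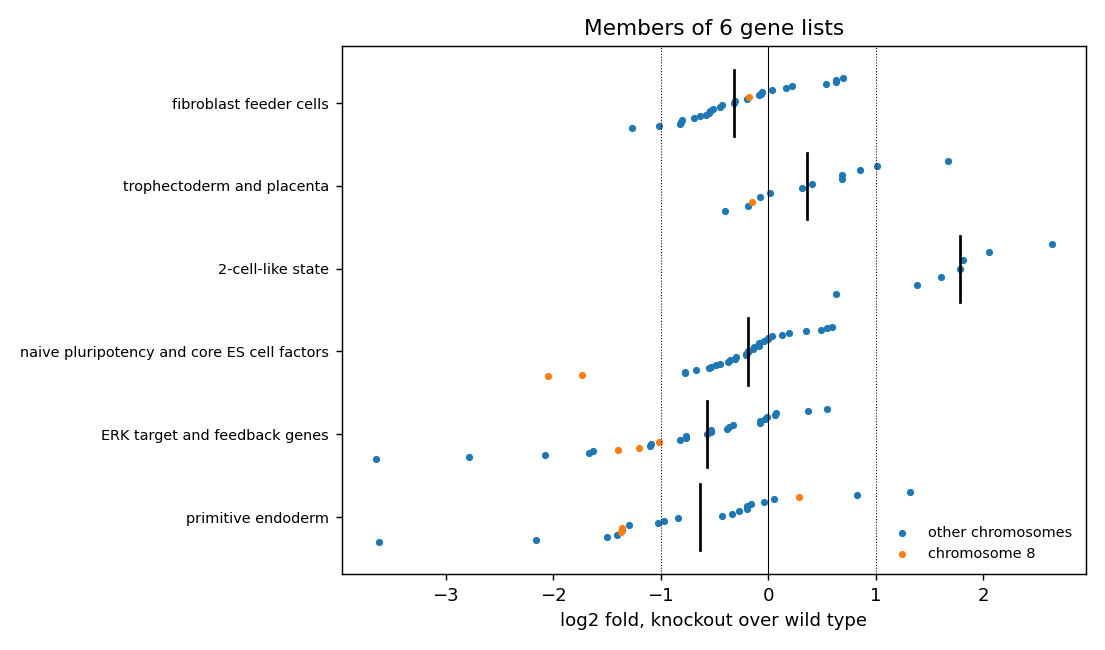
Log2 fold (knockout over wild type) of each measured member of 6 gene lists, 1 point per gene, with chromosome 8 genes in orange, the list median as a black bar and dotted lines at 2-fold. The medians run from -0.63 for primitive endoderm to 1.79 for the 2-cell-like list, whose 6 highest members are Zscan4 genes.

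Other cell types were read from their own lists. The fibroblast list, standing for feeder cells, was lower in the knockout library, with a median of -0.32 over 27 members at percentile 0.01. Of these members 20 were below 0 and 7 above 0. Among the higher ones were Cnn1 (0.70), Tagln (0.63) and Pdgfrb (0.63), named after their values were seen. Col1a1 was at 45.0 and 31.3 CPM, the chemokine gene Ccl2 had a log2 fold of -1.26 and Prrx1 -1.01. This lower level stands beside that of the primitive endoderm list. The mesoderm list had a median of -0.06 (percentile 23.4), with Bmp4 at 32.2% of the wild-type level and Tbx20 at -1.08. Neuroectoderm genes had a median of -0.03 (percentile 26.7), with Nes 2.09-fold higher and Gbx2 at -1.01. Without chromosome 8, which carries Tubb3, that median was 0.18 (percentile 78.8). Vascular genes had a median of -0.15 (percentile 3.84), with Nos3 at -1.30 and Vegfc, which lies on chromosome 8, at -1.02. Without chromosome 8 the vascular median was -0.15 (percentile 3.35). Post-implantation epiblast genes had a median of 0.21 (percentile 96.2), with the claudin gene Cldn6 3.25-fold and Sox11 2.23-fold higher and Foxd3 at 10.7 and 5.07 CPM; with a floor of 5 CPM that median was -0.040.

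Chromatin genes were close as lists. The list of H3K36 methyltransferases, demethylases and readers had a median of -0.03 (percentile 17.5), with Setd2 and Phf19 (-1.16) at least 2-fold lower of 28. DNA methylation and Polycomb genes had a median of -0.08 (percentile 9.07) and 0 of 21 beyond 2-fold. Within it the de novo methyltransferase gene Dnmt3a was at 52.1% (51.2 to 53.1%) and Tet1 at -0.79, while Dnmt3b was at 0.23. Imprinted genes had a median of 0.16 (percentile 94.6). Meg3 was at 4.31% of the wild-type level (3.48 to 5.34%), while Impact was 2.20-fold and Igf2 2.10-fold higher and H19 was at 1.14 and 2.79 CPM, 2.44-fold higher (1.81 to 3.33). Germline genes had a median of 0.23 (percentile 96.9), with Mael at 1.17 and Sycp2 at 1.07.

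Stress response genes (unfolded protein, amino acid and heat shock) had a median of -0.27 over 24 members at percentile 0.05, with 0 beyond 2-fold. Chromosome 8 carried 5 of them, among them Hmox1 (-0.75), and without that chromosome the median was -0.095 at percentile 3.93. Cytosolic ribosomal protein genes had a median of -0.09 over 78 members at percentile 0.14, with 6 at least 2-fold lower, led by Rps12 (-3.34, all windows shared), and Rpl39l higher. Of the other lower members, Rpl29 had 85% of its windows shared, Rpl17 70% and Rpl19 60% (the last 2 named after their values were seen), so the levels of these 4 genes are uncertain. Levels were very unequal over the list, with Rps28 at 1.26 and Rpl4 at 711 CPM in the wild-type library. Both were named after their values were seen. A low share of windows does not show that a member was fully counted, so the list median is uncertain too. The remaining lists lay within the central 95% of random lists. Their medians were 0.12 for p53 targets, 0.10 for DNA repair, 0.07 for cell cycle, 0.07 for Wnt targets, 0.05 for cholesterol synthesis, 0.00 for glycolysis and hypoxia, -0.02 for Nodal, TGF-beta and BMP targets and -0.11 for 5 histone genes. Among the members the rule named were Ccng1 (0.79), Palb2 (0.42), Cdkn2a (-1.27), Lgr5 (1.57), Stard4 (1.00), Ldhb (1.06), Id2 (1.13) and Hist1h2bc (1.54). For Ldhb and Hist1h2bc 55% of windows were shared, so their levels are uncertain. Lgr5, at 0.374 and 2.10 CPM, passed the floor only through the knockout library. No symbol of mitochondrially encoded genes was found, a count of 0. The Y-linked and Xist list had a median of 4.90 over 6 members, a value that depends on the pseudocount, with Tsix at -2.02 and Xist at -0.02, both named after their values were seen. Of 28 lists, 6 medians lay below the 2.5th and 4 above the 97.5th percentile; lists share members, and genes of a list are not independent of each other.

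**Figure D3:**
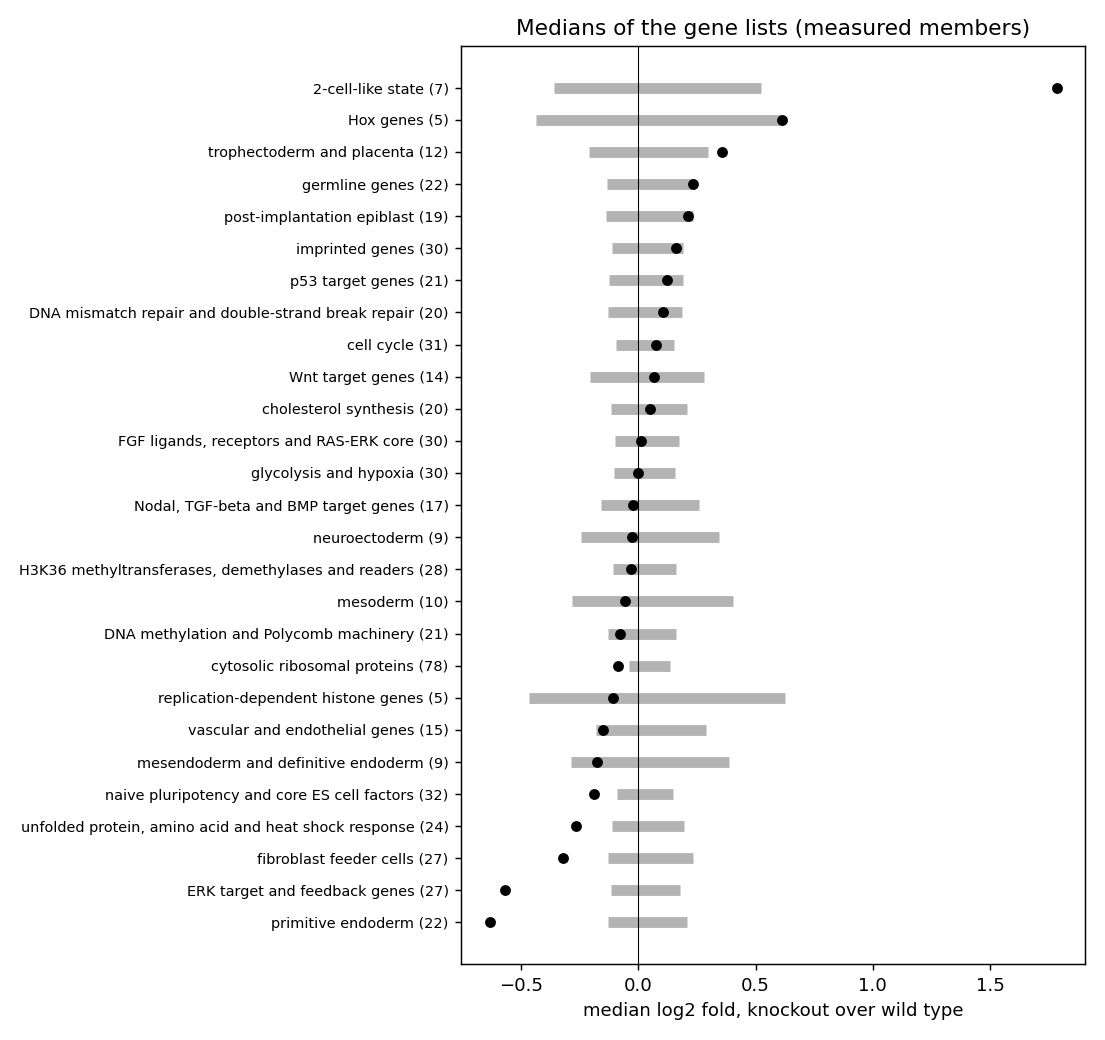
Median log2 fold (knockout over wild type) of each gene list with at least 5 measured members (black points, number of members in brackets), leaving out the Y-linked list, against the central 95% of medians of 10000 random lists matched on mean level (grey bars). Primitive endoderm (-0.63) and ERK targets (-0.57) lie furthest below their bars and the 2-cell-like list (1.79) furthest above.

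Genes of chromosome 8 were lower as a group. The median log2 fold of its 719 genes was -0.35, with quartiles of -0.59 and -0.12, and 82.2% of them were below 0. The medians of the other autosomes ran from 0.00 to 0.13, and that of 506 X-linked genes was 0.17.

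**Figure D4:**
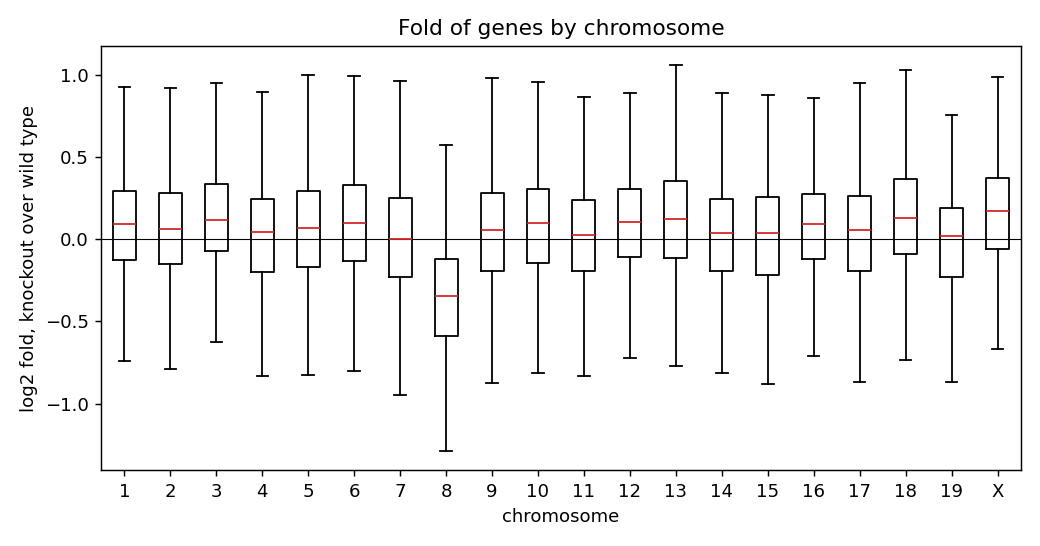
Log2 fold (knockout over wild type) of genes with a mean of at least 1 CPM on each autosome and the X chromosome, as boxes from the lower to the upper quartile with the median in red and whiskers to the last gene within 1.5 box heights; genes beyond the whiskers and the 5 Y-linked genes are not drawn. The median of chromosome 8 (-0.35) lies below those of the others, which run from 0.00 to 0.17, while its box overlaps many of theirs.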

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

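The settings without chromosomes 8 and Y and without genes with shared windows were chosen after the results were seen; the others were fixed before the data were examined. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The Setd2 log2 fold stayed between -1.43 and -1.37; it was -1.43 both with the median log2 ratio set to 0 and with the trimmed mean, outside its narrow counting interval. Of 24 recomputed counts of genes 19 stayed within 1.5 times the reported ones. The number of higher genes was 108 with a floor of 5 CPM. At 1.5-fold 1004 genes were higher and 916 lower, and at 3-fold 62 and 93, as the thresholds themselves imply. The balance of higher and lower genes moved with the setting, from 238 and 285 as reported to 331 and 331 with a pseudocount of 0.1, 204 and 320 with the median log2 ratio set to 0 and 201 and 324 with the trimmed mean. Without chromosomes 8 and Y 231 genes were higher and 245 lower, and without genes with shared windows or no gene model 181 and 231. Of the list medians, 238 of 251 recomputed values moved by less than the spread of random lists. With a floor of 5 CPM, which leaves fewer members, they were -0.040 for post-implantation epiblast, -0.84 for primitive endoderm, -1.60 for mesoderm (Bmp4 alone), 0.63 for the 2-cell-like list (Zfp560 alone, named after its value was seen) and 6.20 for the Y-linked and Xist list. With no filter they were 0.043 for trophectoderm and placenta, 0.64 for the 2-cell-like list and 1.84 for the Y-linked and Xist list. That last list was 6.70 with a pseudocount of 0.1 and 4.05 with a pseudocount of 1. Without chromosomes 8 and Y it was -1.02, since only Xist and Tsix (both named after their values were seen) remain in it, and the medians were -0.43 for primitive endoderm and -0.095 for the stress response. The 28 list percentiles kept their side of the central 95% among genes above 0 in both libraries. Of 1000 recomputed folds of named genes 940 moved by less than their counting error, and 0 of the genes beyond 2-fold changed direction. Vmn2r53, Trmt2a, D16Ertd727e, Zfy1 and Ube1y1, listed at 0 in 1 library, have no finite interval. They could therefore not count as moved, and they are among the 940. Depth limits genes near 1 CPM, where 52.0 to 56.1 read equivalents stand behind a value, and no setting replaces a replicate.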

Other observations

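All tests of the Y-linked genes, the test of Setd2 loss on chromosome 8 and the tests of shared windows split by kind of gene were chosen after the result was seen; the other tests were written down before. Other transcripts of the imprinted region around Meg3 on chromosome 12 were low in the knockout library too, and these genes were chosen after their values were seen, apart from NEWGENE7. NEWGENE7 (110863308 to 110899547) lies within the annotated noncoding gene Rian and over several SNORD113 small RNA genes. It was at 48.3 CPM in the wild-type library and 1.96 CPM in the knockout library, 4.05% of the wild-type level (95% counting interval 3.30 to 4.95%), next to 4.31% for Meg3 (110783608 to 110806809). Rtl1, a paternally expressed gene of that region, was at 0.211 CPM in the knockout library, 10.4% of the wild-type level, and Mirg was listed at 0. Rtl1 lies on the opposite strand to Meg3 and Mirg. Whether strand was used is not known, so reads over Rtl1 may come from either strand and its value need not be that of the paternal transcript.

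Chromosome 8 genes were lower in the knockout library by 0.41 on the log2 scale relative to the other autosomes (bootstrap 95% interval -0.45 to -0.38). The bootstrap intervals in this section resample genes within the 2 libraries as if genes were independent. They give the spread over genes, not that between lines or cultures. All 11 of its 10-Mb bins with at least 20 genes, 100%, had a median at least 0.2 below the other autosomes, so a different number of chromosome 8 copies in part or all of the cells of 1 line is a candidate explanation. GC content is argued against, since the difference was -0.40 after its trend was removed (-0.43 to -0.38). The spread of folds on chromosome 8 was 1.03 times that of the other autosomes, which leaves an even effect of Setd2 loss open, because each genotype is 1 line. Zfp42, Klf2, Vegfc, the primitive endoderm genes Col4a1 and Col4a2 and the ERK targets Ier2, Junb and Dusp4 lie on this chromosome. The last 5 of these were named after their values were seen. Part of the lower level of all these genes may come with the chromosome.

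The Y-linked genes were near 0 in the wild-type library, where the highest stood at 0.305% of its knockout level. That value only restates the pattern, so it does not test whether the wild-type cells lack a Y chromosome. A larger amount of feeder cells in the knockout library is argued against, since the fibroblast list was lower there (median -0.32, bootstrap interval -0.55 to -0.07). Of its members 20 were below 0 and 7 above 0, with Col1a1 at 45.0 CPM in the wild-type and 31.3 CPM in the knockout library. The list does not tell the sex of feeder cells, so it cannot exclude male ones in the knockout culture only. A pair of active X chromosomes in the wild-type line is argued against as well, because X-linked genes were higher in the knockout library by 0.11 relative to the autosomes without chromosome 8 (0.06 to 0.14). Wild-type cells without a Y chromosome stay open as an explanation.

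Outside chromosome Y, 32 genes with a mean of at least 5 CPM were at least 8-fold apart, 28 of them lower in the knockout library. For the first test of shared reads, only 21 of them (65.6%) had a matching gene model, under the 80% needed, so its median share of 0.05 decides nothing. With whole spans added, the 14 genes with ordinary names, such as Arhgap19, Trmt2a and Zfp605, had a median share of 0.025 (0.00 to 0.10). That argues against reads shared within exons for them as a group, though Rps12 had all windows shared. Windows from gene models lay inside single exons, so reads over exon junctions were not tested. The 18 predicted genes and unnamed loci had a median share of 0.625 (0.45 to 0.725), so shared reads may account for part of these, though NEWGENE7 and Gm13042 had none of their windows shared and Gm5421 and Gm6540 25% (the 3 Gm genes named after their values were seen). Genes with a share of at least 0.5 differed from those with none by only 0.071 in median fold (0.044 to 0.095), which argues against a general shift of shared reads but not against effects on single genes; strain variants, deletions, a failure of counting and Setd2 loss stay open for the named genes and were not tested.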
